A study of Homo sapiens with 4 samples.

How the data were processed

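The data are 4 Affymetrix whole-transcript arrays of MV4-11 cells, 1 for each of 4 hairpin RNAs (control, and RUNX1 hairpins labelled moderate, profound 1 and profound 2). Per the labels, cells were transduced with a hairpin, treated with 3 µM doxycycline for 24 h, and total RNA was extracted with a column kit, checked for quality and converted to biotin-labelled cDNA. The deposited table holds log2 signals for 53617 probe sets, processed by the authors with Affymetrix Expression Console 1.3.1, Transcriptome Analysis Console 1.0 and RMA, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays and summarises the probes of a probe set. The settings and the genome build are not given in the sources used here, so no coordinates are printed. Quantile normalisation gives the arrays nearly equal distributions, so a change in total RNA per cell, or one that moves most genes the same way, cannot be seen in these values. RMA also draws dim probe sets toward a floor and understates their differences.

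Groups were taken from the genotype field. The hairpins labelled profound 1 and profound 2 were kept as separate groups because the labels number them as different hairpins. Every column of values was used (0 unused columns). Gene names came from the platform annotation, in which 23871 probe sets have 1 gene symbol, 1842 have several and 27904 have none listed. Of the symbols, 22479 matched the RefSeq gene table of assembly GRCh38.p14 unchanged, 90 were updated through the Entrez ID, 565 through an unambiguous synonym, and 737 were kept as listed. That table was used for names and gene biotypes alone. A probe set with several symbols named no gene, with the exception of the RUNX1 and GSTA2 probe sets, which are printed as shared. Of several probe sets of a gene, the one with the highest mean over the 4 arrays was used, which concerned 475 tested genes. TNF has several probe sets, most of which hold identical values.

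Tested genes had to exceed the median of the table (3.08) in at least 1 array. Symbols of small RNA, predicted, open-reading-frame, antisense and immune receptor segment classes were left out. This left 13047 genes, of which 12344 are protein coding. With 1 array per group, counts rest on a size rule of 2-fold and no test was made. For the arrays labelled profound a gene had to pass in both with the same sign. A member of a gene list was called higher or lower at 1.5-fold. For each array, genes at least 2-fold beyond all other arrays were also counted. The spread quoted for a level is the robust SD (scaled median absolute deviation) of the difference between the array labelled moderate and control within 6 classes of mean level.

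The gene lists number 29, of which 21 are pathway or programme lists and 8 are markers of cell types. They comprise the RUNX family, RUNX1-linked myeloid, glutathione and antioxidant, G1/S, G2/M, CDK inhibitor, p53 target, apoptosis, HOX/MEIS, MYC and ribosome biogenesis, monocyte, granulocyte, interferon, inflammatory, unfolded protein and ATF4, cholesterol, hypoxia, oxidative phosphorylation, stem cell, ribosomal protein and housekeeping lists. The markers are of erythroid, megakaryocyte, B, T and NK, mast, dendritic, fibroblast and epithelial cells. A list's median difference was set against 10000 random lists of the same size, matched on mean level in 20 bins, and stood apart below the 2.5th or above the 97.5th percentile. For the arrays labelled profound it had to do so in both. The percentile describes these arrays and is not a test of conditions.

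The named genes follow a rule. They are the RUNX genes, CBFB and GSTA2; for each of 3 comparisons the 10 genes with the largest difference each way, ranked for the arrays labelled profound by the smaller difference of the same sign; up to 3 members of each list per comparison; the 5 genes standing apart furthest each way in the array labelled moderate; and the 5 that differ most each way between both arrays labelled profound. Y-linked genes and XIST were left out. The grouping, the lists, the thresholds, this rule and the alternatives were fixed before the data were examined, apart from a restriction to protein-coding genes added afterwards.

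Comparisons that share a control array were set against 100 simulated sets of unchanged arrays with the level-dependent spread above. Independent overlap was computed as the product of both counts over the genes tested. The size rule was tested on simulated data for both arrays labelled profound against control (13047 genes, 50 changed at each size). Of genes changed by 1.0 log2 unit 34.0% were recovered at 2-fold and 100.0% at 1.5-fold, and all of those changed by 1.5 or 2.0 were recovered at 2-fold. Of those changed by 0.7, 2.0% were recovered at 2-fold and 70.0% at 1.5-fold. Of 12847 unchanged genes, 0 passed at 2-fold and 0.0467% at 1.5-fold. Every simulated array had the spread of the array labelled moderate against control (robust SD 0.169). Profound 1 spread more (0.265), so these rates may be too favourable for the arrays labelled profound. For the array labelled moderate against control, 39 of 40 simulated lists of 20 genes shifted by 0.2 were recovered, and 5 of 60 unchanged lists fell outside the limits.

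Alternatives comprised centring each array on its median, cyclic loess between arrays, 3 other filters on dim genes, the mean of a gene's probe sets, all genes with 1 symbol, 1.5-fold and 3-fold rules, either array labelled profound alone or their mean, the mean in place of the median of a list, and rank correlation. A further alternative was limma with the arrays labelled profound as 2 replicates of 1 group, which leaves 1 residual degree of freedom and assumes that the lone arrays vary like them. Software comprised Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and limma 3.58.1.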

Results

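Gene expression was measured in MV4-11 cells, an established human acute myeloid leukaemia line with monocytic features that carries a KMT2A-AFF1 fusion. The series asks how expression differs between depths of knockdown of RUNX1, a DNA-binding transcription factor of blood cell development. Cells received 1 of 4 short hairpin RNAs and were kept in 3 µM doxycycline for 24 h. The control hairpin was directed at luciferase and 3 hairpins at RUNX1, of which 1 is labelled a moderate and 2 a profound knockdown (profound 1 and profound 2). RNA of each hairpin was hybridised to 1 whole-transcript array, and the deposited values are log2 RMA signals.

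The 4 arrays had medians between 3.07 and 3.09 log2 units. With 1 array per group, no difference below has a replicate check, differences are not called by p-values, and the number of arrays limits the precision of every value. Genes are therefore named by the size of their difference. As a yardstick, the robust SD of the difference between the array labelled moderate and the control array was 0.25 log2 units among the dimmest of 6 level classes of genes and 0.11 among the brightest. This yardstick holds noise and any real difference together. Over the 13047 tested genes, the robust SD of the difference from control was 0.169 for the array labelled moderate, 0.265 for profound 1 and 0.192 for profound 2, and it was 0.262 between both arrays labelled profound.

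The targeted gene was examined first. RUNX1 is represented by a probe set that is also assigned to LOC100506403, an uncharacterised locus, so its signal is not specific to RUNX1. It read 4.27 in the control array, 4.33 in the array labelled moderate, 4.07 in that labelled profound 1 and 4.04 in that labelled profound 2. The differences from control were 0.06, -0.19 and -0.22 log2 units, which correspond to signals 1.04-fold higher, 1.14-fold lower and 1.17-fold lower. None exceeded the spread of 0.22 for genes of this level. Against the array labelled moderate the differences were -0.25 and -0.28, where the spreads of these pairs at this level were 0.28 and 0.27. Compared with control, 6.58% of the tested genes were lower by at least as much in both arrays labelled profound. The RUNX1 signal thus does not bear out a graded knockdown. In the array labelled moderate it was above control, but within the spread. The arrays are named by their labels throughout, and every direction given below is a direction between labels.

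RUNX3, a second RUNX factor, read 8.17 in the control array and 8.28 in the array labelled moderate, but 7.75 and 7.74 in those labelled profound 1 and profound 2, differences from control of -0.42 and -0.43 log2 units. RUNX2 lay between 6.16 and 6.33 in all 4 arrays. CBFB, the shared partner subunit of RUNX factors, lay between 9.28 and 9.48. The description fields of the arrays labelled profound 1 and profound 2 name RUNX2 and RUNX3 as the targets, whereas their titles and genotypes name RUNX1, which the groups follow. GSTA2, which encodes a glutathione S-transferase, shares its probe set with GSTA1. That probe set read 1.76 in the control array, 2.55 in the array labelled moderate, 1.58 in profound 1 and 1.35 in profound 2, all below the median of all probe sets (3.08). The separate GSTA1 probe set was lower than control in all 3 arrays of RUNX1 hairpins, with differences of -0.48, -0.53 and -0.63 log2 units.

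**Figure D1:**
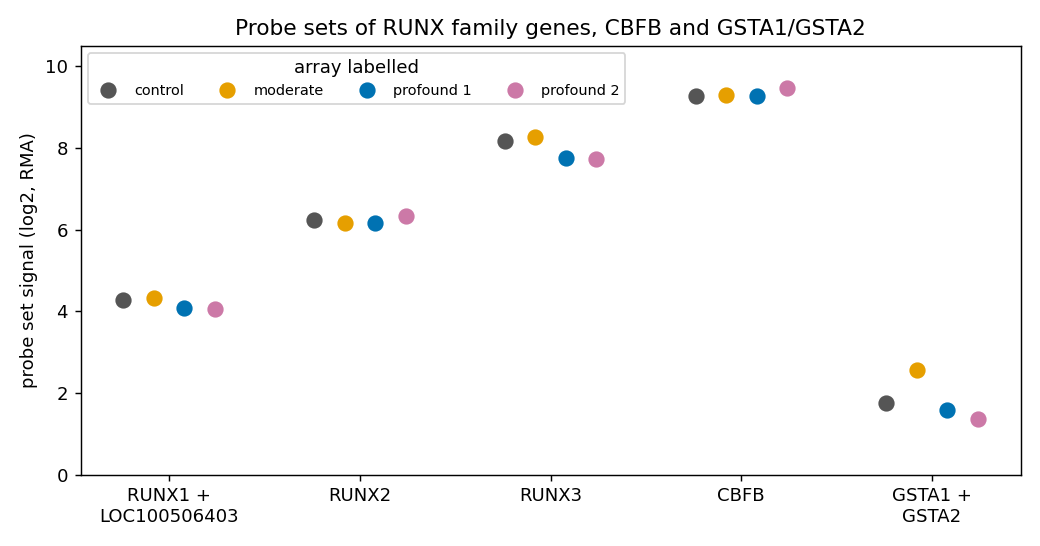
Probe set signal (log2 RMA, vertical axis from 0) of RUNX1, RUNX2, RUNX3, CBFB and the shared GSTA1 and GSTA2 probe set, with 1 point per array, coloured by label. RUNX1 lies between 4.04 and 4.33 in all 4 arrays, and RUNX3 is lower in both arrays labelled profound (7.75 and 7.74) than in the control array (8.17).

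The array labelled moderate was then compared with the control array. GAPT, a GRB2-binding membrane adaptor of blood cells, was higher there (4.88 to 6.17), as were the Wnt antagonist gene DKK4 (2.22 to 3.40) and CTSE, which encodes the aspartic protease cathepsin E (3.39 to 4.50). SDC4, a cell-surface heparan sulphate proteoglycan, was lower (3.83 to 2.52), as was GBP4, an interferon-inducible guanylate-binding protein gene (4.18 to 3.09). In all, 12 of 13047 genes differed at least 2-fold, 7 higher and 5 lower. The other higher genes were FAM106A (1.32 log2 units), ZNF502 (1.05), SPATA31J1 (1.01) and ACTA1 (1.01), and the other lower ones were the pseudogenes RPL36P20 (-1.17) and PDE4DIPP6 (-1.01) and the histone gene H2AC1 (-1.04). Just below 2-fold lay SULT1B1, a sulfotransferase gene (0.98), CLIC2 (0.98) and CES1, a carboxylesterase of monocytes and macrophages (0.94), on the higher side. On the lower side lay GOLGA6L5P (-0.86), DUSP4, a MAP kinase phosphatase gene (-0.82), ULK4P3 (-0.82), IL20RB (-0.82) and the water channel gene AQP5 (-0.79). CES1 had a control level of 7.92, but the 12 genes had a median level at only the 7.86th percentile of the tested genes, and the count was 6 when the mean over the arrays had to exceed the table median and 1 under a 75th-percentile filter. At 1.5-fold the count was 185 genes, 122 higher and 63 lower.

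Of the 29 gene lists, 6 stood apart from random lists of the same size and level in the comparison of the array labelled moderate with control. Lists of independently drawn genes give 1.45. Members of a list can vary together between single arrays, so 6 against 1.45 is not evidence of an excess. Monocyte and macrophage genes were shifted upward, with a median of 0.15 log2 units at the 99.9th percentile of random lists. Of 21 measured members, 1 was at least 1.5-fold higher, the integrin gene ITGAX (0.63), and none lower. ITGAX read 3.02 in control, below the table median, so its difference is that of a dim probe set. The immunoreceptor adaptor gene FCER1G (0.56) and the calprotectin gene S100A8 (0.54) lay just under that size. Granulocyte and primary granule genes had a median of 0.14 at the 99.8th percentile, with 0 of 16 members at 1.5-fold; CSF3R, the G-CSF receptor gene, was at 0.50, the granule protein gene BPI at 0.43 and the granule protease gene CTSG at 0.34, whereas CST7, a cystatin gene, was at -0.41. This call was lost without the filter on dim genes (83.0th percentile) and narrowly with the mean of the list (97.3rd percentile).

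Cell-cycle lists lay below control in the same array. G1/S and DNA replication genes had a median of -0.18, below all 10000 random lists, led by the cyclin gene CCNE2 (-0.52), the replication licensing gene CDC6 (-0.43) and CLSPN (-0.40). G2/M and mitosis genes had a median of -0.11, also below every random list, led by KIF23 (-0.32), UBE2C (-0.27) and the survivin gene BIRC5 (-0.27). None of the 29 and 28 members reached 1.5-fold. MYC and ribosome biogenesis genes had a median of -0.07 (0.70th percentile, 0 of 20 members at 1.5-fold), and housekeeping genes one of -0.09 (1.24th percentile, 0 of 11 members). The housekeeping call was lost after cyclic loess (3.51st percentile) and with the mean of the list (11.0th percentile).

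Both arrays labelled profound were compared with the control array next, and a gene was counted only where both differed in the same direction. CD38, a NAD-consuming ectoenzyme and differentiation marker of blood cells, was the 1 gene at least 2-fold different in both, at 3.78 in control against 4.79 and 5.23. SORL1, a sorting receptor gene, was higher by 1.25 and 0.95 log2 units, FCER2, the low-affinity IgE receptor CD23, by 0.93 and 0.99, and DEPTOR, an mTOR inhibitor gene, by 1.15 and 0.88. CLEC10A, a galactose-type lectin gene of macrophages and dendritic cells, was lower (5.43 against 4.06 and 4.56), as were the organic anion transporter gene SLCO4C1 (5.62 against 4.39 and 4.67) and RACGAP1, a cytokinesis regulator (4.55 against 3.01 and 3.61). At 1.5-fold, 90 genes differed in both arrays, 45 higher and 45 lower.

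The remaining genes with the largest differences on the higher side were SMIM14 (1.82 and 0.90 log2 units), the lysosomal channel gene MCOLN2 (0.94 and 0.84), the leukocyte protease inhibitor gene SLPI (1.01 and 0.83), the sphingosine phosphate receptor gene S1PR5 (0.87 and 0.82), ITGAX (1.13 and 0.80) and LRRC25 (1.02 and 0.79). On the lower side they were ESPNP (-0.83 and -1.28), RRN3P1 (-0.83 and -0.93), WAKMAR2 (-0.79 and -0.85), FAM86JP (-0.78 and -0.88), LSP1P3 (-0.91 and -0.78), the tetraspanin gene TSPAN13 (-0.97 and -0.76) and ZNF484 (-0.84 and -0.76). RRN3P1, FAM86JP and LSP1P3 read below the table median in both arrays labelled profound, and ESPNP did in profound 2. ITGAX (3.02) and S1PR5 (2.93) read below it in the control array. The differences of all these genes are those of dim probe sets. The difference of CD38 in profound 1 was 0.99 after cyclic loess, which leaves 0 genes at 2-fold in both. The single arrays differed from control at 2-fold in 105 genes (profound 1) and 11 genes (profound 2).

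**Figure D2:**
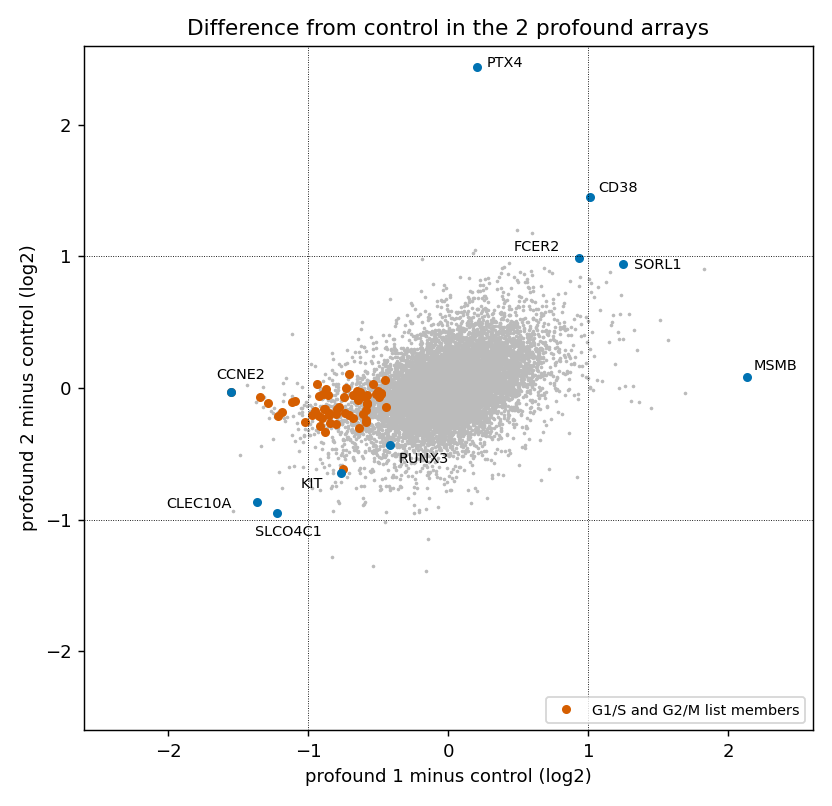
Log2 difference from the control array in profound 1 (horizontal) against profound 2 (vertical), with 1 grey point for each of the 13047 tested genes, orange points for the members of the G1/S and G2/M lists, blue points for the genes written beside them and dotted lines at 2-fold. CD38 is the 1 gene beyond 2-fold in both arrays, and the cell-cycle genes lie far to the left (list medians of -0.88 and -0.70) but near 0 on the vertical axis (-0.14 and -0.08).

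Among the gene lists, 7 stood apart from random lists in both arrays labelled profound against control, 2 upward and 5 downward. Both arrays are set against the same control array, so these are not independent results. The monocyte, granulocyte, G1/S and G2/M lists stood apart the same way in the array labelled moderate. None of these lists stood apart from that array in both arrays labelled profound. For them a deviation of the control array was not separated from a shared shift, except for the cell-cycle lists in profound 1. Against the array labelled moderate, the G1/S and G2/M medians of profound 1 were -0.65 and -0.56 (both at the 0.0th percentile). Those of profound 2 were 0.04 and 0.01 (90.0th and 67.2nd percentiles). The control array does not enter these values. They argue against its deviation as the whole cause of the lower G1/S and G2/M lists in profound 1. Monocyte and macrophage genes had medians of 0.13 and 0.15, at the 97.9th percentile or higher in both. Of 21 members, 2 were at least 1.5-fold higher in both, ITGAX and CD68, a lysosomal glycoprotein gene of macrophages (0.70 and 0.63). ITGAX read below the table median in control (3.02). No member was lower at that size in both, and MS4A7 was at 0.80 and 0.45. Without the filter on dim genes the profound 2 array lay at the 96.5th percentile. Granulocyte and primary granule genes had medians of 0.18 and 0.11, although their 1 member at 1.5-fold in both was lower, the myeloid lectin receptor gene CLEC5A (-0.72 and -0.67). CLEC5A is near the floor, at 3.35 in control and 2.62 and 2.67 in both others, so its differences are uncertain. Short of 1.5-fold in both, BPI (0.51 and 0.52) and the neutrophil elastase gene ELANE (0.41 and 0.37) lay above control. CST7 (-0.45 and -0.75) and CTSG (-0.56 and -0.14) lay below it, also short of 1.5-fold in both. The granulocyte call was lost without the filter on dim genes (62.3rd percentile in profound 1), with the mean of the list (90.6th and 63.8th) and after cyclic loess (96.4th in profound 2).

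Haematopoietic stem cell genes were lower in both arrays labelled profound, with medians of -0.30 and -0.23 (0.120th and 0.260th percentiles). Of 10 measured members, 2 were at least 1.5-fold lower in both: the receptor kinase gene KIT (-0.77 and -0.65) and the transcription factor gene GATA2 (-0.60 and -0.88). GATA2 is near the floor, at 3.15 in control and 2.54 and 2.27 in both others, so its differences are uncertain. NRIP1, a nuclear receptor corepressor gene (-0.49 and -0.57), and the homeobox gene MEIS1 (-0.33 and -0.25) were smaller in difference. The mast cell and basophil list had medians of -0.69 and -0.62 (0.01st and 0.02nd percentiles). It rests on 4 measured members, of which 2 are KIT and GATA2. The IgE receptor gene FCER1A was at -1.14 and -0.60 and PRG2 at -0.08 and -0.22. FCER1A read 2.76 in profound 1, below the table median. With the filter on the mean level, which leaves GATA2 out, both lists still stood apart (stem cell medians -0.27 and -0.21, mast cell medians -0.77 and -0.60). Without the filter on dim genes neither list stood apart in both arrays (28.4th and 18.7th percentiles in profound 1).

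Cholesterol synthesis genes had medians of -0.36 and -0.19 (0.02nd and 0.170th percentiles) in the arrays labelled profound 1 and profound 2, against -0.03 in the array labelled moderate. Of 17 measured members, 3 were 1.5-fold lower in profound 1 and 0 in profound 2. The sterol isomerase gene EBP was at -0.64 and -0.33, HSD17B7 at -0.68 and -0.36 and the sterol oxidase gene MSMO1 at -0.53 and -0.34. HSD17B7 read 2.62 and 2.94 in the arrays labelled profound 1 and profound 2, below the table median. The inflammatory list as a whole was within the central 95% of random lists in every array, but 2 of its 18 members were 1.5-fold lower in both arrays labelled profound: the cytokine gene TNF (-0.80 and -0.74) and TNFAIP3, an inhibitor of NF-kB signalling (-0.63 and -0.74).

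Cell-cycle genes differed in extent between the arrays labelled profound. In profound 1, 25 of 29 G1/S and DNA replication genes were at least 1.5-fold lower than in control and the median was -0.88. In profound 2, 1 of 29 was (UHRF1, -0.75 in profound 1 and -0.61 in profound 2) and the median was -0.14. CCNE2 read 7.97 in control, 6.41 in profound 1 and 7.94 in profound 2, and CDC6 was at -1.29 and -0.12 (profound 1 and 2). Of 28 G2/M and mitosis genes, 21 were 1.5-fold lower in profound 1 (median -0.70), including the proliferation antigen gene MKI67 (-0.88), CCNB2 (-0.85) and UBE2C (-0.89). In profound 2 none was (median -0.08, 0.480th percentile), and MKI67 was at -0.33. Both lists still stood below random lists in both arrays.

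Set directly against each other, the arrays labelled profound 1 and profound 2 differed at least 2-fold in 68 genes, 31 higher and 37 lower in profound 1, and at 1.5-fold in 696. This is more than either the array labelled moderate (12) or profound 2 (11) differed from control, but fewer than profound 1 did (105). Profound 1 also differed from the array labelled moderate in 54 genes. The genes furthest below profound 2 in profound 1 were PTX4, a pentraxin gene (3.48 against 5.71), CCNE2 (6.41 against 7.94), ATP5F1EP2 (-1.53 log2 units), the mitotic phosphatase gene CDKN3 (7.27 against 8.73) and TFDP1, a dimerisation partner of E2F factors (5.94 against 7.28). Those furthest above were MSMB (4.50 against 2.46), AKAIN1 (1.73 log2 units), the arrestin-domain gene ARRDC3 (1.60), the galanin receptor gene GALR2 (1.60) and OTOA (1.47). MSMB, AKAIN1 and OTOA read 2.46, 2.01 and 2.45 in profound 2, below the table median, so their differences are those of dim probe sets. The same holds for ATP5F1EP2, which read 1.84 in profound 1. Lists lower in profound 1 than in profound 2 were G1/S (-0.68), G2/M (-0.55), MYC and ribosome biogenesis (-0.26), unfolded protein and ATF4 response (-0.31) and cholesterol synthesis genes (-0.22). The HOX/MEIS leukaemia programme (0.14, 98.7th percentile) and glutathione and antioxidant genes (0.11, 99.0th percentile) were higher, and the HOX/MEIS call was lost with the mean of the list (96.2nd percentile) and under a 75th-percentile filter (96.3rd percentile). The 15 of 22 HOX/MEIS genes measured include no HOX gene, since none of the 7 HOXA members has a probe set of 1 symbol, and MEIS1 itself was lower in profound 1 than in profound 2 (-0.09). That call therefore rests on other members such as HMGA2 (0.26) and MYB (0.22), the latter chosen after its values were seen.

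Some lists stood apart from control in 1 of the arrays labelled profound alone. In profound 1, glutathione and antioxidant genes had a median of 0.10 (97.9th percentile), with 4 of 27 members 1.5-fold higher, the haem oxygenase gene HMOX1 (6.14 in control against 7.44, chosen after its values were seen), the cystine transporter gene SLC7A11 (0.72), the glutathione reductase gene GSR (0.61) and GSTA4 (0.63). GSTA4 read 3.07 in control, just below the table median. In profound 2 the median of the list was -0.01, with 0 members at 1.5-fold higher and 2 lower. There HMOX1 was at -0.09 and SLC7A11 at -0.61, while GSR (0.37) and GSTA4 (0.56) lay above control, short of 1.5-fold. Unfolded protein and ATF4 response genes had a median of -0.32 in profound 1, with 5 of 22 members lower, among them the serine synthesis gene PHGDH (-1.25) and the asparagine synthetase gene ASNS (-0.76), and 1 higher. In profound 2 their median was 0.01. PHGDH (-0.39) and ASNS (-0.47) lay below control there and in the array labelled moderate (both -0.49), short of 1.5-fold. MYC and ribosome biogenesis genes (-0.18) and megakaryocyte and platelet genes (-0.29 over 6 members, 4.64th percentile when the mean had to exceed the table median) were lower in profound 1 only, and dendritic cell genes (-0.18 over 8 members, 1.40th percentile) in profound 2 only. Whether these lists differ between the arrays was examined only by the direct comparison given above, where the megakaryocyte (16.7th percentile) and dendritic cell (76.5th percentile) lists stayed within the central 95%.

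**Figure D3:**
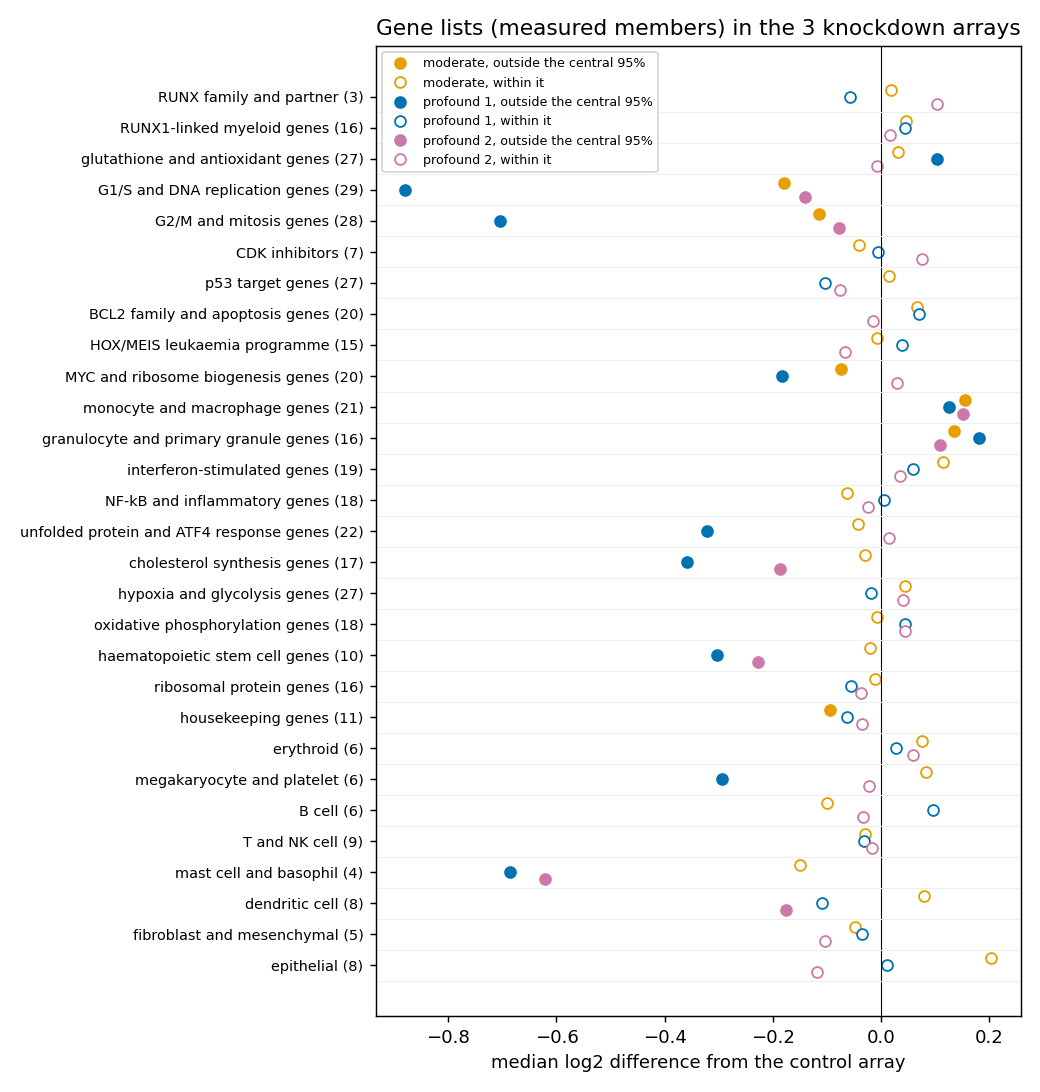
Median log2 difference from the control array (horizontal axis) of the measured members of each of the 29 gene lists, with the number measured in brackets and 1 point each for the arrays labelled moderate, profound 1 and profound 2. Filled points lie outside the central 95% of 10000 random lists of matched level; the G1/S list is at -0.18, -0.88 and -0.14.

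The comparison of both arrays labelled profound with the array labelled moderate addressed the depth of knockdown as labelled. FCER2 was at 5.53 in the array labelled moderate against 7.01 and 7.06, and SEL1L3 at 5.55 against 6.80 and 6.97. CD72, a B cell co-receptor gene also found in myeloid cells, was at 5.25 against 3.84 and 4.10, and DKK4 at 3.40 against 1.95 and 2.09. With CD38 (3.73 against 4.79 and 5.23) and ZNF484 (-1.12 and -1.04 log2 units), these were the 6 genes at least 2-fold different in both, 3 higher and 3 lower. At 1.5-fold there were 107, 42 higher and 65 lower. DKK4 lay below the table median in both arrays labelled profound, so its difference is that of a dim probe set.

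Among the further genes of this comparison, MMP2, a gelatinase gene, read 8.34 in the array labelled moderate and 7.42 and 7.33 in those labelled profound, the ribonuclease gene RNASE6 read 8.07 against 7.17 and 6.86, the tissue factor gene F3 7.21 against 6.09 and 6.31, and the interleukin receptor gene IL7R 7.14 against 5.94 and 6.27. SIGLEC9 (-1.30 and -0.89), CTSE (-0.98 and -1.06) and ESPNP (-0.87 and -1.33) were also lower in those labelled profound. CD68 read 9.14 against 9.98 and 9.91 and the proton pump subunit gene ATP6V1E1 6.71 against 7.56 and 7.51. SDC4 (0.89 and 1.44), GBP4 (0.87 and 1.32), H6PD (1.34 and 0.82), HIC1 (0.83 and 1.08) and GOLGA2P7 (0.83 and 0.95) were higher. Of the gene lists, 2 stood apart in both. They were cholesterol synthesis genes (-0.33 and -0.18) and haematopoietic stem cell genes (-0.22 and -0.20, with 1 of 10 members at 1.5-fold). The stem cell call was lost under both other level filters and with the mean of the list, and without the filter on dim genes its median in profound 1 was 0.02.

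Genes with an extreme level in 1 array were counted alike for each array. Against all 3 other arrays, 0 genes stood apart at 2-fold in the control array, 1 in that labelled moderate (DKK4), 19 in profound 1 (5 higher, 14 lower) and 2 in profound 2 (PTX4 higher, ANKRD20A1 lower, the latter named after its value was seen). At 1.5-fold the numbers were 7, 27, 255 and 47. DKK4 read 2.22 in control, 1.95 in profound 1 and 2.09 in profound 2, all below the table median. It passed the filter through the array labelled moderate alone, so its difference is that of a dim probe set. After DKK4, the array labelled moderate stood furthest above the other 3 for CTSE (0.98 log2 units from the nearest array), GAPT (0.79), the actin-binding protein gene CORO2A (0.76) and the potassium channel gene KCNK17 (0.75). It stood furthest below them for SDC4 (-0.89), GBP4 (-0.87), FOXD4L1 (-0.72), the dynein light chain gene DYNLT1 (-0.66) and ATP6V1E1 (-0.65). All 3 arrays of RUNX1 hairpins together differed from control at 2-fold in 0 genes and at 1.5-fold in 7, 5 higher and 2 lower, among them ITGAX, SMIM14, RACGAP1 and DUSP4.

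The remaining lists stayed within the central 95% of random lists for the array labelled moderate and did not stand apart in both arrays labelled profound against control. RUNX1-linked myeloid genes had medians of 0.05, 0.04 and 0.02 in the arrays labelled moderate, profound 1 and profound 2, with the M-CSF receptor gene CSF1R at 0.29, -0.11 and 0.16. Medians for p53 target genes were 0.02, -0.10 and -0.08, for BCL2 family and apoptosis genes 0.07, 0.07 and -0.01, and for CDK inhibitors -0.04, -0.01 and 0.07. The p53 target gene FAS was at 0.12, -0.57 and -0.37 and BCL2 at -0.12, -0.39 and -0.36. Interferon-stimulated genes had medians of 0.12, 0.06 and 0.04, and OAS2 was at 0.79, 0.29 and 0.09. The 1 member of 19 at 1.5-fold in both arrays labelled profound was lower, the ISG15 protease gene USP18 (-0.35, -0.94 and -0.61). Hypoxia and glycolysis (0.04, -0.02 and 0.04), oxidative phosphorylation (-0.01, 0.04 and 0.04) and ribosomal protein genes (-0.01, -0.06 and -0.04) were near 0, as was the RUNX family list (0.02, -0.06 and 0.10 over 3 members). Among markers of other cells, medians were 0.08, 0.03 and 0.06 for erythroid genes, -0.10, 0.10 and -0.03 for B cell genes and -0.03, -0.03 and -0.02 for T and NK cell genes. They were -0.05, -0.03 and -0.10 for fibroblast and mesenchymal genes and 0.20, 0.01 and -0.12 for epithelial genes, the first of which lay just inside the upper limit. The inflammatory medians were -0.06, 0.00 and -0.02. Against the array labelled moderate, some of these lists stood apart downward in 1 array: p53 target (-0.19, 0.40th percentile) and interferon-stimulated genes (-0.25, 0.10th percentile) in profound 1, and RUNX1-linked myeloid (-0.11, 1.60th percentile) and BCL2 family and apoptosis genes (-0.14, 2.11th percentile) in profound 2.

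Across genes, which are not independent replicates, the differences from control in profound 1 and profound 2 correlated with a Pearson r of 0.442 and a Spearman rho of 0.430. Simulated unchanged arrays that share 1 control give an r of 0.4995. That value follows from giving every simulated array the same spread, that of the array labelled moderate against control (0.169). Profound 1 spread more (0.265), so the observed r cannot be read as below the share of a common control. For the same reason the simulated overlaps below may be too low. The covariance of both differences from control was 0.0318 against 0.0174 simulated, a difference of 0.0144. For the array labelled moderate the r was 0.450 with profound 1 (rho 0.451, covariance 0.0114 above the simulated value) and 0.365 with profound 2 (rho 0.352, covariance -0.0002 from it). Of 361 genes higher at 1.5-fold in profound 1 and 163 in profound 2, 45 were shared, where independent lists give 4.51 and simulated unchanged arrays 4.34. Of 529 and 150 lower genes, 45 were shared, against 6.08 and 4.17. The array labelled moderate shared 32 of its 122 higher genes with profound 1 (3.38 and 4.30 by these measures) and 17 with profound 2 (1.52 and 4.42). Of its 63 lower genes it shared 9 with profound 1 (2.55 and 4.28) and 10 with profound 2 (0.724 and 4.33). A single control array cannot be split, so the share of each excess that comes from the common control was not separated.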

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

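The tests of the cell-cycle genes, of the control array and of dim probe sets in this part were all chosen only after the results they bear on were seen. No group holds enough arrays for a check of arrays far from their group.

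Among the named genes, 19 moved one way from control in the array labelled moderate and the other way in both arrays labelled profound. Each difference exceeded the spread of its level, which is that of the array labelled moderate against control. Profound 1 spread more (0.22 against 0.11 in the brightest class). ODC1 (0.12), PLAUR (-0.15), ATP6V1E1 (0.20) and EDA2R (-0.24) lay within the spread of profound 1 at their level. The differences of the 19 genes were not tested. Higher in the array labelled moderate and lower in both others were CD72 (0.64 log2 units in the array labelled moderate), SIGLEC9 (0.48), RNASE6 (0.48), ITGA2B (0.43), EDA2R (0.34), CTSG (0.34), MMP2 (0.33), IL7R (0.30), ZNF484 (0.28), F3 (0.26), PLAUR (0.18), TCF4 (0.15) and RUNX3 (0.11). Lower there and higher in both others were ATP6V1E1 (-0.65), FCER2 (-0.55), SEL1L3 (-0.54), HIC1 (-0.51), CD68 (-0.14) and ODC1 (-0.14). Over all 13047 tested genes 98 met the same condition, where simulated unchanged arrays give 11.9. The simulated arrays all have the narrower spread, so 11.9 may be too low. Part of the named genes were chosen for a large difference between these arrays, which favours the condition.

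The comparisons above leave out probe sets with no listed symbol. Among the 12094 of them that pass the filter, 162 were at least 2-fold different from control in both arrays labelled profound, 43 higher and 119 lower, which is 1.34% against 0.0077% of the tested genes. These probe sets scatter more: 3.49% were 2-fold different in the array labelled moderate, and the robust SD of that difference was 0.277 against 0.169. Between both arrays labelled profound 588 of them differed 2-fold. The filter also admits dim probe sets that are high in the control array alone. That favours lower values in both arrays set against this control, so the larger number of lower ones cannot be interpreted.

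The first pattern is the lower level of cell-cycle genes in profound 1 than in profound 2. Level-dependent scaling is argued against, since other tested genes of the same level had a median of -0.0141 log2 units between these arrays (-0.0242 to 0.0314 over the level bins), against -0.63 over the 57 members (quartiles -0.77 and -0.47). Undirected scatter of a noisier array is also argued against, since 100.0% of the members were lower in profound 1. Deeper loss of RUNX1 with that hairpin stays open. The RUNX1 probe set was 0.0301 log2 units higher in profound 1 than in profound 2. This is not the direction of a deeper loss, but it lies within the spread of 0.22. An effect of the hairpin on other transcripts and a difference in culture growth also stay open and were not tested.

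The second pattern is the set of 90 genes at least 1.5-fold different from control in both arrays labelled profound. A deviation of the control array alone was weighed as the whole cause. Along each gene's direction the mean of both arrays lay a median of 0.51 log2 units from the array labelled moderate as well (quartiles 0.34 and 0.66), against 0.74 from control. Simulated unchanged arrays give 0.22, and 88 of the 90 kept their sign. The simulation gave every array the spread of the array labelled moderate against control (0.169), whereas profound 1 spread more (0.265). With a wider spread the choice of genes alone gives more than 0.22, so how far the values argue against this cause was not settled. Only 23 of the 90 were also 1.5-fold different from the array labelled moderate in both, so a contribution of the control array to the others stays open. A difference tied to the hairpins is a candidate explanation that 1 array per hairpin cannot separate from a difference between cultures.

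The last pattern is the set of 12 genes at least 2-fold different between the array labelled moderate and control. Scatter of dim probe sets stays open as a cause. The median level of these genes lay at the 7.86th percentile of the tested genes (quartiles 0.424 and 21.2), where spread is widest. A 2-fold difference is well beyond the robust SD of 0.25 in the dimmest class, so scatter would need wider tails than that SD implies. Such tails were seen among probe sets with no listed symbol. Of these, 3.49% were 2-fold different in the same comparison at a robust SD of 0.277. A low level alone cannot show scatter, since the filter also admits dim genes that are high in 1 array. The test does not exclude a real difference for single genes, such as GAPT at the 43.1st percentile.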

How the results depend on the processing

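The restriction to protein-coding genes is the 1 alternative here chosen only after the results were seen, and it moved no total by over 1.5 times, although the genes 2-fold lower in the array labelled moderate went from 5 to 3. No paired analysis was possible because each group has 1 array and all carry the same replicate number. With 1 array per group no array could be left out within a group. The signal over background limits dim genes most, and the cause of the shifts below was not tested except where a rule itself sets the number of genes that pass.

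Filters on dim genes test fewer or more genes. Genes 2-fold different in the array labelled moderate against control (12) became 6 where the mean had to exceed the table median and 1 under the 75th-percentile filter, and those standing apart in that array (1) became 0 under both. Those standing apart in profound 2 (2) became 1 under the 75th-percentile filter. With all genes of 1 symbol the counts were 27 for the array labelled moderate against control, 7 for both arrays labelled profound against control, 14 for both against the array labelled moderate, and 1 for all 3 against control. Standing apart were then 1 in control, 3 in the array labelled moderate and 6 in profound 2.

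The 1.5-fold rule gave 185 genes for the array labelled moderate against control, 90 and 107 for both arrays labelled profound against control and against the array labelled moderate, 7 for all 3 against control and 696 between both arrays labelled profound. Standing apart were then 7 (control), 27 (moderate), 255 (profound 1) and 47 (profound 2). The 3-fold rule gave 0 genes for each of the first 3 comparisons, 5 between both arrays labelled profound, and 0, 1 and 1 standing apart in those labelled moderate, profound 1 and profound 2.

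Requiring only 1 array labelled profound gave 105 (profound 1) or 11 (profound 2) genes against control and 54 or 31 against the array labelled moderate, and the mean of both gave 11 and 21. The limma alternative called 0 genes at adjusted p under 0.05 in each of 3 comparisons (smallest adjusted p 0.9999, 0.9998 and 0.667), with 178, 427 and 419 at unadjusted p under 0.05.

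Cyclic loess left 0 genes in both arrays labelled profound against control, since CD38 in profound 1 went from 1.01 to 0.99. It left 1 gene standing apart in profound 2, as did centring, 1 higher and 0 lower against 1 and 1 before. It also took the granulocyte list out of those above random lists, so that 1 stood above and 5 below in both arrays labelled profound, and 1 and 6 in profound 2. Neither scaling moved the median of all genes by over 0.1 log2 units.

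Of 7 lists standing apart in both arrays labelled profound against control, 3 did so without the filter on dim genes. Of 2 against the array labelled moderate, 1 did so without the filter, and 1 under each of the other filters. The stem cell list reversed there without the filter, with a median of 0.0192 in profound 1, and lost its call under the other 2 filters and with the mean. The mast cell and megakaryocyte lists give no value under the 75th-percentile filter, with under 3 members left.

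The correlations moved by under 0.1 and the RUNX1 differences by less than their spread in each alternative run. All 1296 differences of named genes kept within their spread under centring and under cyclic loess, and 1270 did with the mean of a gene's probe sets, where 14 moved and 12 have no value because the gene falls below the filter.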

Other observations

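Of the tests in this part, the one on a graded response was chosen before its result was seen, and the gene families were chosen only after the data were seen.

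Replication-dependent histone genes were lower in profound 1, as the cell-cycle lists were, but not in profound 2. Their 26 measured members had a median difference from control of -0.42 log2 units in profound 1, below every random list, with 11 at least 1.5-fold lower. The medians were -0.05 in the array labelled moderate and 0.04 in profound 2, with 2 and 0 members 1.5-fold lower. Directions were the same after centring and cyclic loess. Histone genes are similar in sequence, so single members are uncertain.

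Small nucleolar and Cajal body RNAs, which the tested genes leave out, were lower in the array labelled moderate (median -0.18 over 152, below every random list) and in profound 1 (-0.11), and at 0.00 in profound 2. Cathepsin genes, which encode lysosomal proteases, were higher in the array labelled moderate (median 0.22 over 13, 99.99th percentile) and at 0.13 and 0.04 in the arrays labelled profound, within the central 95%. Zinc finger genes with ZNF symbols (413) had a median of -0.11 in profound 2, below every random list, against 0.04 in profound 1, above most random lists (98.9th percentile), and 0.02 in the array labelled moderate, where it turns to -0.01 after centring. MHC class II genes (14) were at 0.12, -0.04 and 0.13, within the central 95% in all 3 arrays. Of these medians, the one for ZNF genes in the array labelled moderate was the only one of the 5 families against control that changed sign under centring or cyclic loess.

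A hypothesis was tested that the 107 genes 1.5-fold different between the array labelled moderate and both labelled profound form a graded series, with control beyond the array labelled moderate. On a scale with that array at 0 and the mean of both labelled profound at 1, control lay at a median of 0.472 (quartiles 0.287 and 0.770), and below 0 for 5 genes. A value above 0.1 was set beforehand as evidence against a graded series, but that bound was wrong: unchanged arrays alone give 0.669, because genes picked for an extreme value in the array labelled moderate fall back in any other. The observed value lies below the simulated one and above 0, so a graded and a non-graded response cannot be told apart here.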
